A study of Mus musculus with 16 samples.

How the data were processed

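Liver RNA of 16 db/db mice was profiled by RNA sequencing, 8 mice after an adeno-associated virus (AAV8) encoding enhanced green fluorescent protein (GFP) and 8 after the same type of vector encoding arcA. Per the labels' protocols, littermate mice were injected at about 5 weeks of age, liver was taken 5 weeks later, total RNA was isolated with Trizol, and oligo-dT was used. The deposited values are raw read counts per gene symbol, 1 column per library. Per the submitters' processing notes, the reads were handled with bcl2fastq, STAR 2.5.1a and featureCounts 1.4.6-p5 of the Subread package on the mouse build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The table held 40757 lines of counts. Of these, 348 were exact copies of another line and were removed, and 85 of the remaining 40409 repeated a symbol with 47 counts in all. Of the 40324 distinct symbols, 40247 were found in the GENCODE M21 annotation of GRCm38, from which coordinates and gene types were taken by symbol; it may differ from the annotation behind the counts.

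Total counts ranged from 28912600 to 53520800 per library. Among counts from 1 to 20, 69.8% were even (68.1% to 71.4% per library), as counting both mates of a read pair separately would give. How mates were counted is not given in the sources used here, so the number of independent fragments behind a count is uncertain. If mates were counted separately, folds given against a counting floor would be lower. Counting floors (3 counts) cover counting error only, and reads without molecular identifiers are not independent molecules. Within groups, the chi-square statistic per gene between 2 libraries lay between 24.3 and 673 over 56 pairs, far above sampling noise, so each library counted as 1 sample. The labels do not state the sex of the mice. Xist had 0 to 4 counts and the Y-linked Ddx3y 936 to 3934 counts in each library, the pattern of male mice, and no library stood apart by sex. No line was named for arcA or GFP, and transgene expression was not analysed here.

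Groups were taken from the labels. The test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, robust dispersion fit, TMM scaling), with the group as its only term, on the 14476 genes that passed filterByExpr, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are arcA over GFP on the log2 scale. CPM values were computed from the deposited counts with TMM-scaled library sizes, and a prior count of 2 was used for log2 CPM. For genes with 0 counts in one group, the fold is given against a floor of 3 counts over the whole group. The 54 gene lists (pathways, cell type markers, other tissues and quality measures) were fixed before the data were examined; 51 had at least 5 tested genes. They were tested with camera of limma 3.58.1 (two-sided, preset inter-gene correlation of 0.01, Benjamini-Hochberg over the lists), beside camera with the correlation estimated per list, and fry. Counts of list members are given over all genes tested and adjusted over the list alone.

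Genes were named by a rule set before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 1 CPM and at least 7 of 8 arcA libraries on that side of the GFP median, leaving out predicted-gene and clone names. It added up to 4 members with the smallest p of each list described, and Fgf21, Arg1, Ass1, Cps1, Asns, Map1lc3b, Sqstm1, Fasn, Scd1, Srebf1, Pck1, Cpt1a, Cyp7a1 and Alb whatever their p. Sdc1, Uroc1, Hk3, Cyp2b13, Gm42418 and Lars2 were named outside the rule, after their values were seen. Some genes that the rule takes are not reported here.

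Alternatives fixed before the data were examined were RLE and upper-quartile scaling, library size alone, no filter, a filter of 1 CPM in at least 8 libraries, DESeq2 1.42.0, limma voom with quality weights, surrogate variables from sva 3.50.0, a replicate block, a minimum fold of 1.5, and each library left out in turn. Added after seeing the data were fits without GFP 2, 3 and 5, without arcA 3 and 8, with counts halved, without Gm42418 and Lars2, and scaled on hepatocyte marker genes. To see how many of the higher genes stay called with fewer libraries, each of the 56 sets of 3 GFP libraries was left out in turn, also added after seeing the data. The pipeline was tested on simulated counts for the 14476 genes of the comparison of arcA with GFP. It recovered 64.2% of genes changed 1.5-fold (43 of 67), 88.1% of those changed 2-fold (59 of 67) and 100% of those changed 4-fold (66 of 66), and called 7 of 14235 unchanged genes. A raised list was called, and so was 1 of 50 other lists. The changed genes were drawn only from genes above a minimum mean count, so the recovery does not cover weakly expressed genes. Simulated genes varied independently of each other, so the list result does not show how often lists of correlated genes are called falsely.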

Results

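The series measured liver gene expression in db/db mice, which lack a working leptin receptor and become obese and diabetic. One group of 8 mice received AAV8 encoding GFP as the control, and the other group of 8 received AAV8 encoding arcA. The labels do not say what arcA encodes; among other uses, it is the name of a bacterial gene for arginine deiminase, an enzyme that breaks down arginine. All livers came from mice aged 10 weeks, 5 weeks after injection. Libraries held 38691000 ± 7495000 counts in the GFP group (SD, n = 8; range 28912600 to 53520800) and 41220000 ± 2752800 in the arcA group (SD, n = 8; range 37325600 to 45874800). The first principal component, 47.2% of the variance of the most variable genes, separated the groups without overlap (-30.7 to -11.2 in GFP and 9.85 to 26.2 in arcA livers). Gm42418, which overlaps ribosomal RNA sequence, took 11.8%, 18.1% and 19.4% of counts in GFP 2, 3 and 5, against 2.29% to 7.37% in the other libraries.

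The comparison asked how arcA expression changed the liver transcriptome relative to GFP. Genes of T cells, plasma cells, lipid-associated macrophages and monocytes were lower in arcA livers, together with chemokine and extracellular matrix genes. Rises were smaller, among them those of C3, the fibrinogen genes and some cytochromes P450. In all, 618 genes were higher and 951 lower in arcA livers, 10.8% of the 14476 tested. The median log2 fold change was 0.267 for the higher and -0.802 for the lower genes. At least 2-fold changes numbered 17 up and 330 down. The groups did not overlap at all for 81 of the higher and 173 of the lower genes, where chance gives 0.016% of genes. Without GFP 2, 3 and 5, the counts were 369 higher and 818 lower, and without arcA 3 and 8 they were 527 and 1100. Without GFP 2 alone, 389 genes were higher. Scaling by library size alone gave 253 higher and 800 lower, so that 24.0% of the calls were rises in place of 39.4%. Scaling on hepatocyte markers gave 94 higher and 2729 lower, 3.33% of them rises.

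The 12 largest falls were nearly all immunoglobulin genes. Ighg1, the constant region of IgG1 heavy chains (chromosome 12, 113325240 to 113330523, GRCm38), fell by 10.41 on the log2 scale (SE 0.897, adjusted p = 9.91e-06), from 104 ± 98.6 to 0.0728 ± 0.0781 CPM (SD, n = 8 each). Ighg2c fell by 9.28 (SE 0.524, adjusted p = 1.33e-07), Ighg2b fell by 6.86 and Igha fell by 4.91. The kappa light chain constant gene Igkc (chromosome 6, 70726435 to 70726966) fell by 6.53 (SE 0.461), from 99.8 ± 74.2 to 1.08 ± 0.329 CPM. Jchain, which joins IgA and IgM units, fell by 5.66. Among variable segments, Igkv12-46, Igkv12-44 and Igkv6-23 had log2 fold changes of -8.17, -8.04 and -6.43. All 4 arcA counts of Igkv12-44 came from arcA 8, and its value was -10.3 without that library and -14.2 with surrogate variables, so its size is uncertain. Ighv1-63 had 1339 counts over the GFP group and 0 over the arcA group, at least 462-fold lower, and Ighv8-12 had 1029 and 0, at least 355-fold lower. GFP 7 had 14.5 CPM of Ighv1-63 and the other GFP livers 0.67 to 3.89, so its bound rests largely on GFP 7. Mmp12, a macrophage elastase, fell by 4.46 (SE 0.506, adjusted p = 5.81e-05). All 12 lay below the GFP median in 8 of 8 arcA livers. Immunoglobulin genes share near-identical sequence, so the split of reads among them is uncertain. The call of Ighv1-63 was lost with surrogate variables.

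The largest rises had smaller folds. Serpinb1c, a serine protease inhibitor gene (chromosome 13, 32881434 to 32898211), rose by 2.65 (SE 0.364, adjusted p = 0.000249), from 0.545 ± 0.304 to 3.39 ± 1.46 CPM (SD, n = 8 each), and its neighbour Serpinb1a rose by 1.06. Of the cytochromes P450, Cyp3a41b rose by 2.09 (SE 0.593, adjusted p = 0.0368), Cyp2c69 by 1.93, Cyp3a41a by 1.87 and Cyp2c40 by 1.26. GFP 1 and GFP 7 had the lowest GFP values of each of these genes, with 3.12 and 4.75 CPM of Cyp2c69 against 11.1 to 30.7 in the other GFP livers. The highest values of Cyp3a41b and Cyp3a41a were those of arcA 7 (81.8 and 182 CPM), so the sizes of these rises lean partly on single livers. The transporter genes Slc13a2 (dicarboxylates and citrate) and Slc22a26 rose by 1.76 and 1.63. Fam19a2, Eci3, Cnmd and Mapk15 rose by 1.23, 1.15, 1.12 and 0.88. Mapk15 was above the GFP median in 7 of 8 arcA livers and the other 11 in 8 of 8. Cyp3a41a with Cyp3a41b, Cyp2c69 with Cyp2c40, and Serpinb1a with Serpinb1c are close paralogs, so their separate folds are uncertain. The calls of Cyp3a41b, Cyp2c40 and Mapk15 were lost in 8, 6 and 12 of the 16 fits without 1 library (adjusted p up to 0.0735, 0.057 and 0.0719). Without GFP 2, 3 and 5, these 3 and Cyp2c69, Cyp3a41a and Slc22a26 lost the call.

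Lymphocyte markers fell most among the lists. All 17 tested T and natural killer cell genes fell (17 adjusted over the list alone), with a median log2 fold change of -2.98, and the median was the same with Pdcd1 at its bound. Cd8b1, part of the CD8 co-receptor, fell by 3.82 (SE 0.26, adjusted p = 4.9e-08) and Cd8a fell by 4.84 (SE 0.367), in 8 of 8 arcA livers. Gzma, a cytotoxic granule protease, fell by 4.25. Pdcd1, which encodes the inhibitory receptor PD-1, had 317 counts over the GFP group and 0 over the arcA group, at least 109-fold lower. Of 8 tested B and plasma cell genes, 6 fell and 1 rose, with the same counts adjusted over the list alone, at a median of -2.31. Igkc and Jchain fell as above, Iglc2 fell by 3.59 and the plasma cell gene Mzb1 fell by 3.17. The gene that rose was Sdc1, at 0.37; it is also expressed by hepatocytes, and its call was lost without GFP 7 (adjusted p = 0.051). Both lists kept their call with an estimated correlation (adjusted p = 0.000161 and 0.00819).

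Macrophage and monocyte genes fell as well. Of 14 lipid-associated macrophage genes, 7 fell (9 adjusted over the list alone, where 2 also rose), at a median of -1.08. With a filter of 1 CPM in at least 8 libraries, which tests fewer genes, this median was -0.385 and that of the B and plasma cell list -1.35, and both lists stayed called. Among them Lgals3 (galectin-3) fell by 1.99 (SE 0.196), Cd63 fell by 1.38 and Gpnmb fell by 2.75, beside Mmp12. Of 11 monocyte genes, 7 fell (8 adjusted over the list alone, where 1 rose), at a median of -1.05, with S100a4 at -1.99, Plac8 at -0.70, Cx3cr1 at -1.05 and Ly6c2 at -1.52. Both lists kept their call with an estimated correlation (adjusted p = 0.0171 and 0.0444). Of 22 Kupffer cell and macrophage genes, 11 fell (16 adjusted over the list alone), at a median of -0.67, among them Clec7a, a receptor for fungal glucans (-2.72), Lyz2 (-0.86), Ctss (-0.95) and Msr1 (-0.56). The list had an adjusted p of 0.287 with an estimated correlation. Of 12 genes of MHC class II and dendritic cells, 8 fell (9 adjusted over the list alone), at a median of -1.52, with H2-DMb1 at -1.51, Itgax at -2.31, H2-Ab1 at -1.80 and the invariant chain gene Cd74 at -1.63. Its adjusted p was 0.0741 with an estimated correlation. Lyz2 and Ctss lay below the GFP median in 7 of 8 arcA livers.

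**Figure D1:**
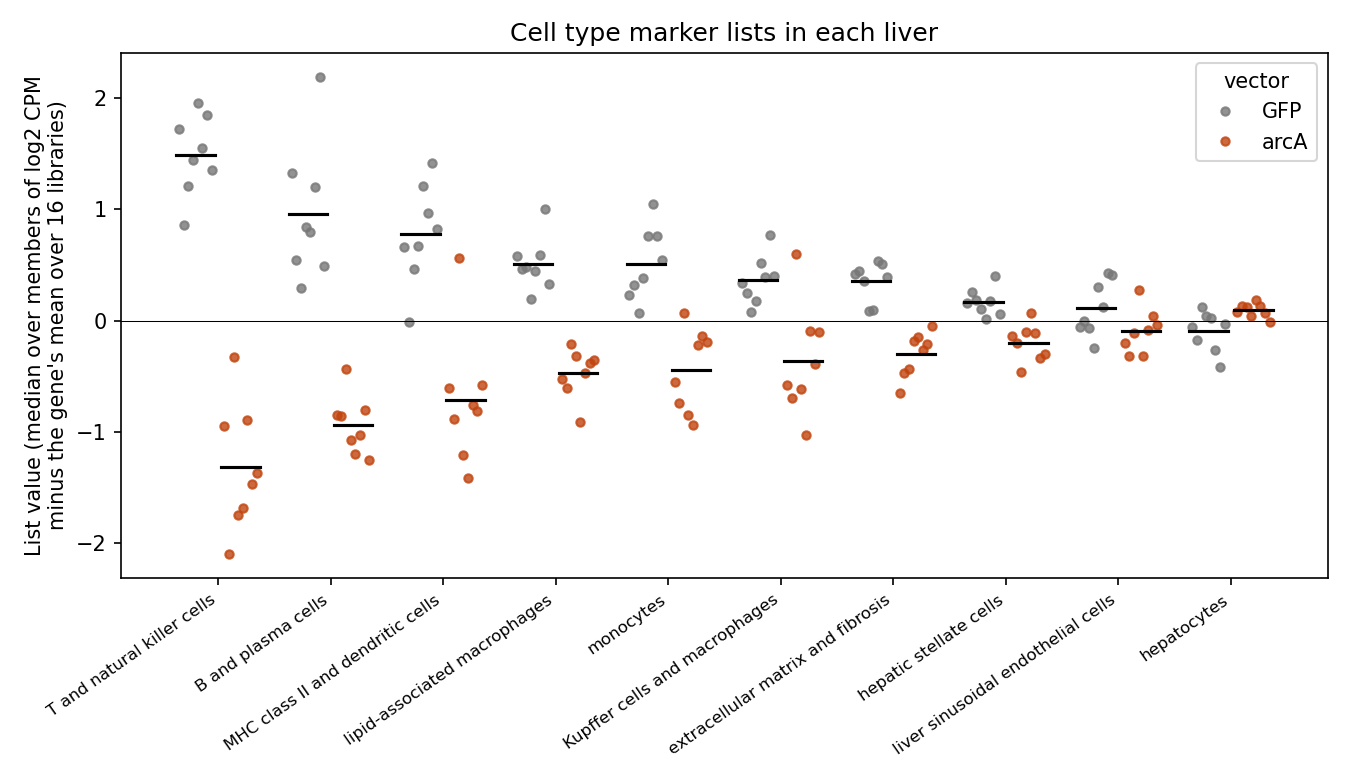
Values of 10 cell type or matrix lists in each liver, 8 GFP (grey) and 8 arcA (orange). Each point is 1 library's median over list members of log2 CPM minus the gene's mean over the 16 libraries, and black bars are group means; T and natural killer cell genes lie farthest apart, and hepatocyte genes differ little.

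Of 22 inflammatory cytokine and chemokine genes, 10 fell (13 adjusted over the list alone), at a median of -0.66. The T cell attractant genes Ccl4 and Ccl5 had log2 fold changes of -4.49 (SE 0.459) and -4.13 (SE 0.395), the adhesion molecule gene Vcam1 of -1.62 and Cxcl16 of -0.97. The list kept its call with an estimated correlation (adjusted p = 0.0289). Of 42 interferon-stimulated genes, 16 fell (21 adjusted over the list alone), at a median of -0.45, and the adjusted p of the list was 0.273 with an estimated correlation. Cxcl10, a chemokine induced by interferon-gamma, fell by 2.13 (SE 0.168, adjusted p = 1.66e-07), from 5.25 ± 1.30 to 1.20 ± 0.268 CPM (SD, n = 8 each). The interferon-induced GTPase gene Igtp fell by 1.32 and Sp100 fell by 0.68. Of 16 genes of antigen processing and MHC class I, 2 fell (3 adjusted over the list alone), Psmb9 (-0.76) and Tap1 (-0.54), at a median of -0.19. The adjusted p was 0.592 with an estimated correlation and 0.128 with fry.

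Extracellular matrix genes fell together. Of 36 extracellular matrix and fibrosis genes, 20 fell (30 adjusted over the list alone, where 1 rose), at a median of -0.62, and the list kept its call with an estimated correlation (adjusted p = 0.0171). Dcn (decorin) fell by 0.50 (SE 0.0636, adjusted p = 5.56e-05), from 142 ± 9.40 to 101 ± 10.9 CPM (SD, n = 8 each). Col14a1 fell by 0.65 and Bgn (biglycan) fell by 0.47, beside Mmp12. Of 18 markers of hepatic stellate cells, the main collagen-producing cells of the liver, 9 fell (11 adjusted over the list alone), at a median of -0.36, with Tagln at -0.70 and Pdgfrb at -0.57. The list had an adjusted p of 0.0741 with an estimated correlation. Of 21 markers of liver sinusoidal endothelial cells, 1 fell (also 1 adjusted over the list alone), Lyve1 (-0.77), and the list median was -0.22. Its adjusted p was 0.592 with an estimated correlation and 0.104 with fry. The call of Lyve1 was lost with surrogate variables.

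**Figure D2:**
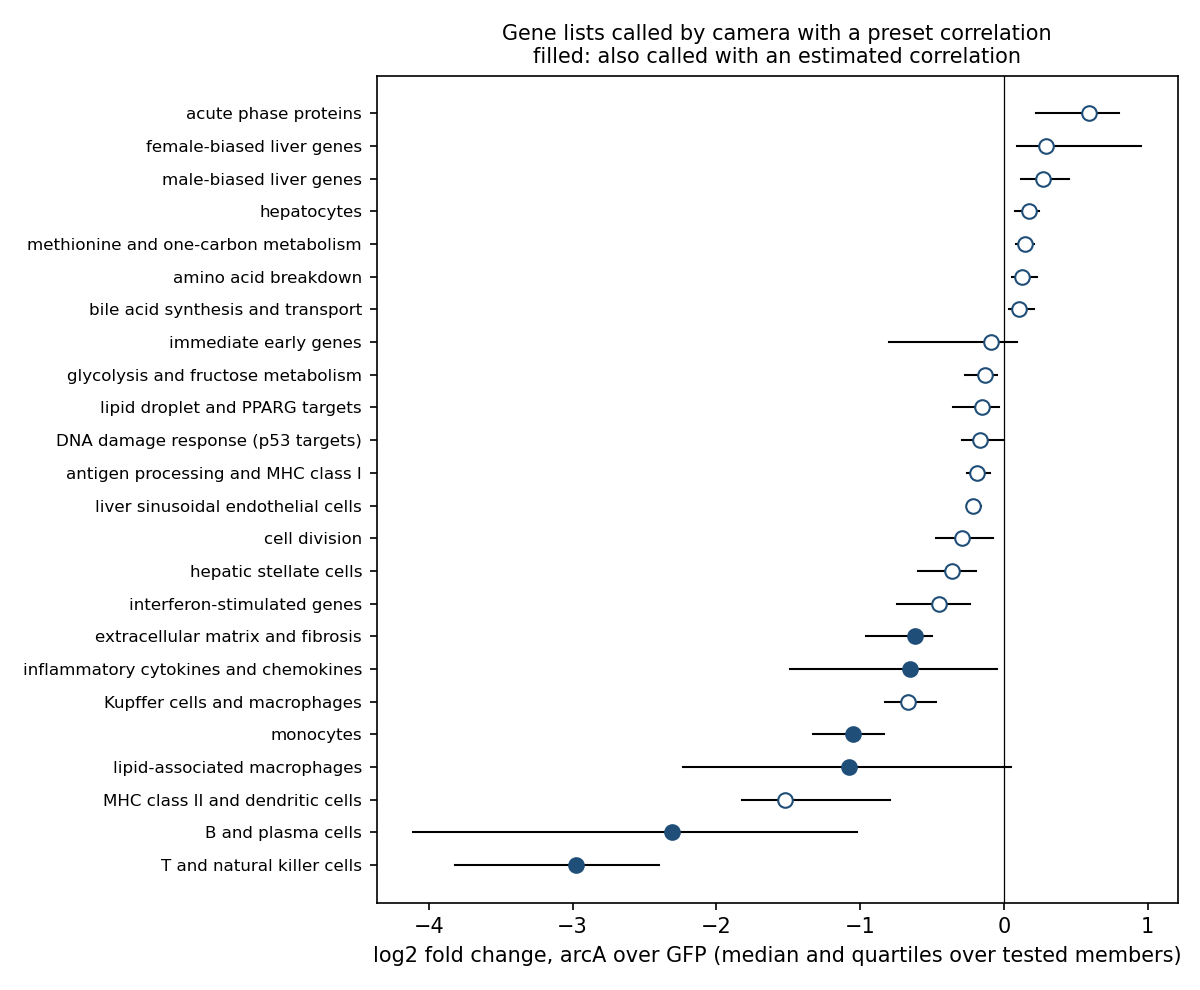
Median log2 fold change (arcA over GFP) of the 24 lists called by camera with a preset correlation, with bars from the lower to the upper quartile over tested members. Filled points mark the 6 lists also called with an estimated correlation, which all lie below 0; the 7 lists above 0 are open.

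Of 30 tested acute phase genes, 4 rose (5 adjusted over the list alone), at a list median of 0.59. The list was called with the preset correlation, but its adjusted p was 0.592 with an estimated correlation, 0.152 with fry and 0.767 without arcA 3 and 8, where its median was 0.037; it was 0.29 with the replicate block. C3, the central complement component, rose by 0.74 (SE 0.154, adjusted p = 0.0043), from 6290 ± 1200 to 10520 ± 2890 CPM (SD, n = 8 each). The fibrinogen genes Fga, Fgb and Fgg rose by 0.67, 0.64 and 0.60. All 4 were above the GFP median in 8 of 8 arcA livers. Of 19 hepatocyte markers, 3 rose (4 adjusted over the list alone), Fga, Fgb and Cyp2e1 (0.37), at a median of 0.18. With an estimated correlation, its adjusted p was 0.493. Alb, the albumin gene, had a log2 fold change of 0.18 (SE 0.0829, adjusted p = 0.186), and Ttr of 0.28 (adjusted p = 0.0697). Ttr passed with DESeq2, with limma voom, without arcA 8 (0.34, adjusted p = 0.00565) and without arcA 3 and 8.

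In the list of urea cycle and arginine transport or breakdown, 0 of 18 tested members passed with edgeR, over all genes or adjusted over the list alone. Of these, 5 had an unadjusted p under 0.05, and 2 passed with DESeq2 and 2 with limma voom. The adjusted p of the list was 0.189. The log2 fold change was 0.18 for Ass1 (SE 0.0985, adjusted p = 0.261), 0.21 for Cps1 (SE 0.131, adjusted p = 0.343), -0.14 for Arg1 (SE 0.195, adjusted p = 0.727), 0.17 for Nags and 0.23 for Otc. When 1 library was left out, Ass1 ranged from 0.13 to 0.22, Cps1 from 0.12 to 0.25 and Arg1 from -0.28 (without GFP 5) to -0.10. Nags passed with limma voom and without arcA 6 (adjusted p down to 0.0302), and Otc without arcA 8 and without arcA 3 and 8 (adjusted p down to 0.0341). Of 33 amino acid breakdown genes, 5 rose (9 adjusted over the list alone), at a median of 0.13, which was 0.075 without GFP 7. The adjusted p of this list was 0.592 with an estimated correlation, 0.055 with fry and 0.0942 with surrogate variables. Mccc2 and Ivd, of leucine breakdown, rose by 0.23 and 0.24, Pccb and Mut, of propionate breakdown, by 0.16 and 0.18, and Uroc1, of histidine breakdown, by 0.23. Of 18 genes of methionine and one-carbon metabolism, 4 rose (also 4 adjusted over the list alone), Cbs by 0.32, Mthfd1 by 0.21, Aldh1l1 by 0.30 and Pemt by 0.19, at a median of 0.14. The list had an adjusted p of 0.43 with an estimated correlation. Scaling on hepatocyte markers turned both medians negative and ended the calls of Mccc2 and Cbs, though camera still called both lists higher (adjusted p = 0.00272 and 0.000935); Cbs also lost its call without arcA 3 and 8. The calls of Ivd, Pccb, Mut, Uroc1, Aldh1l1 and Pemt were lost in 7, 8, 10, 12, 11 and 14 of the 16 fits without 1 library (adjusted p up to 0.115), and that of Mthfd1 without arcA 6 (adjusted p = 0.0531).

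**Figure D3:**
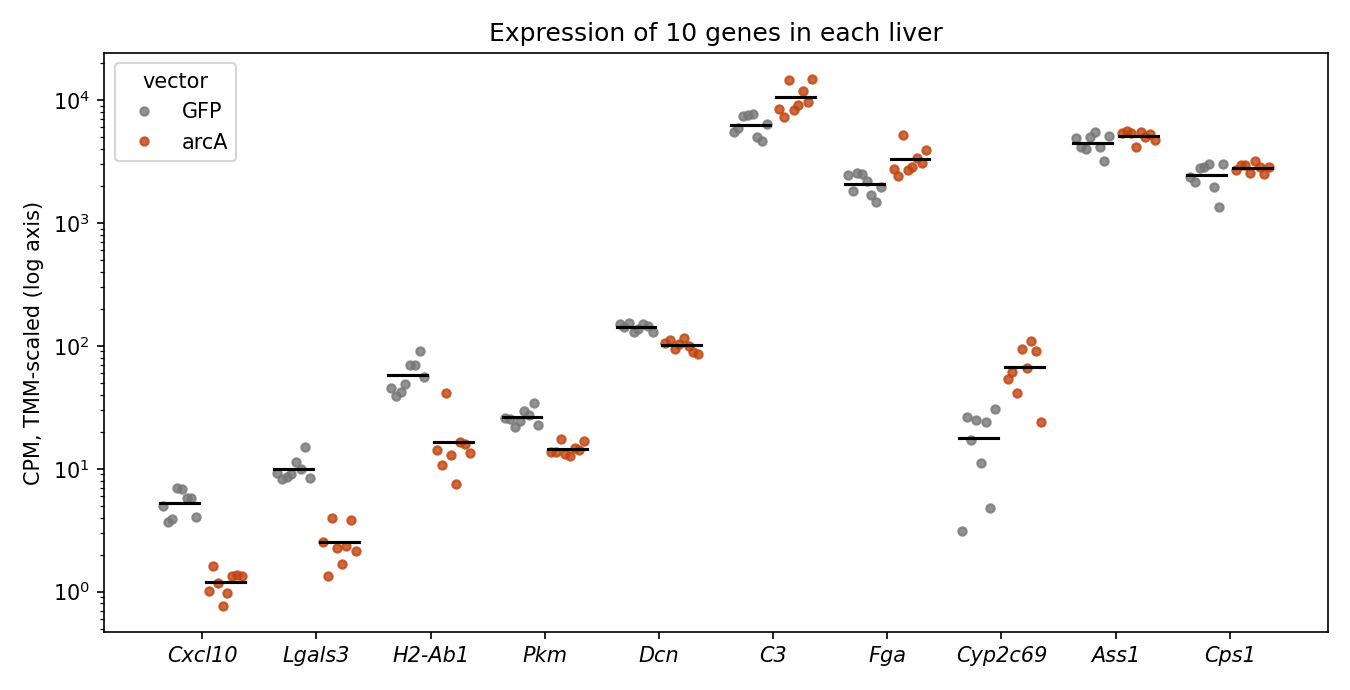
TMM-scaled CPM (log axis) of 10 genes in each of 8 GFP (grey) and 8 arcA (orange) livers, with black bars at group means. Cxcl10, Lgals3, Pkm and Dcn are lower in each arcA liver than in each GFP liver, while Ass1 and Cps1 overlap between the groups.

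Of 25 targets of ATF4, the transcription factor of the amino acid stress response, 4 fell and 0 rose (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.466), except with fry (adjusted p = 0.0376). Atf3 fell by 1.61, Pck2 fell by 0.84, Aldh18a1 fell by 0.81 and Psat1 fell by 1.07. Fgf21, a hepatic hormone gene, and Asns, asparagine synthetase, were below the filter, with 285 and 51 counts over the GFP group and 63 and 46 over the arcA group. For Fgf21, GFP 7 held 114 of the GFP counts, GFP 3, 4, 5 and 8 had 6 to 11 each, and arcA livers had 0 to 16. With no filter its log2 fold change was -2.03 (adjusted p = 0.051), and it passed with DESeq2 (-2.03, adjusted p = 0.00315). Fgf21 also passed in each fit without 1 library where it met the filter (-2.20 to -1.86, adjusted p up to 0.0451). None of these fits left out GFP 1, 2, 5, 6 or 7 or arcA 2 or 6, the libraries with the most Fgf21 counts. Without any of these the gene stayed below the filter, so passing in the other fits does not show that the call is robust. Without GFP 2, 3 and 5 it passed (-2.14, adjusted p = 0.0363), and without arcA 3 and 8 it did not (-1.91, adjusted p = 0.0688). Asns did not pass with no filter or with DESeq2 (adjusted p = 0.888 and 0.886). Of 32 autophagy genes, 2 rose (1 adjusted over the list alone), Atg9a by 0.25 and Ulk2 by 0.21, and the list was not called (adjusted p = 0.165). Map1lc3b and Sqstm1, which encode autophagy proteins, had log2 fold changes of 0.075 (adjusted p = 0.361) and 0.086 (adjusted p = 0.484), and ranged from 0.045 to 0.094 and from 0.045 to 0.13 when 1 library was left out. Of 36 lysosome genes, 4 rose, among them Scarb2 by 0.23 and Gaa by 0.22, and Ctss fell, with 6 and 2 adjusted over the list alone (list adjusted p = 0.0752, below 0.05 without arcA 1 or arcA 2). The calls of Atg9a and Scarb2 were lost without GFP 2, 3 and 5 and with scaling by library size alone or on hepatocyte markers. The calls of Psat1, Ulk2 and Gaa were lost in 10, 13 and 10 of the 16 fits without 1 library (adjusted p up to 0.108), and that of Aldh18a1 without GFP 7 (adjusted p = 0.0502).

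Lipid genes moved in small numbers. Of 25 lipid droplet and PPARG target genes, 3 fell (4 adjusted over the list alone), at a median of -0.15. The adjusted p of the list was 0.592 with an estimated correlation, 0.128 with fry, 0.241 with surrogate variables and 0.0712 without arcA 3; its median was -0.098 without GFP 2 and -0.096 without GFP 7. Lpl, lipoprotein lipase, fell by 1.62 (SE 0.204, adjusted p = 0.000198), Apoa4 fell by 1.02 and Plin4, a lipid droplet coat gene, fell by 0.95. Lpl is also a member of the lipid-associated macrophage list, so its fall is counted in both. Plin4 lost its call without arcA 1 (adjusted p = 0.0516). Of 26 genes of fatty acid and triglyceride synthesis, 2 rose (also 2 adjusted over the list alone), Mlxipl by 0.49 and Dgat2 by 0.31, and both lost the call without GFP 2, 3 and 5. Fasn, fatty acid synthase, had a log2 fold change of -0.58 (SE 0.311, adjusted p = 0.267), Scd1 of 0.069 (SE 0.431, adjusted p = 0.946) and Srebf1 of 0.12 (adjusted p = 0.749; 0.0059 to 0.23 when 1 library was left out). With surrogate variables, Fasn passed at -0.41 (adjusted p = 0.0124) and Scd1 at 0.60 (adjusted p = 0.0414). Of 25 cholesterol genes, Ebp rose by 0.38 (also the only 1 adjusted over the list alone). Of 40 genes of fatty acid oxidation and ketone synthesis, 1 rose (0 adjusted over the list alone), and Cpt1a had a value of -0.092 (adjusted p = 0.662; -0.16 to -0.018 when 1 library was left out). These 3 lists were not called (adjusted p = 0.516, 0.345 and 0.297). Over 28 alternatives, the synthesis list was called with surrogate variables (adjusted p = 0.0345), the cholesterol list without GFP 1 (adjusted p = 0.00686), and the oxidation list with surrogate variables and without arcA 3 and 8.

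Of 25 genes of glycolysis and fructose metabolism, 5 fell (8 adjusted over the list alone), at a median of -0.13. Its adjusted p was 0.43 with an estimated correlation. Pkm, the pyruvate kinase gene of most non-hepatocytes, fell by 0.86 (SE 0.0872, adjusted p = 4.67e-06), and the hexokinase genes Hk2, Hk1 and Hk3 had log2 fold changes of -1.33, -0.53 and -1.01. Aldoa fell by 0.23. Hk1 lost the call without GFP 2, 3 and 5 and with surrogate variables, and Aldoa and Hk3 lost it in 9 and 13 of the 16 fits without 1 library (adjusted p up to 0.0993). Pck1, a gluconeogenic enzyme gene, had a log2 fold change of 0.060 (adjusted p = 0.868). Of 25 genes of bile acid synthesis and transport, 3 rose (also 3 adjusted over the list alone), Slc27a5 by 0.37, Abcc3 by 0.28 and Nr5a2 by 0.24, at a median of 0.11. The adjusted p was 0.554 with an estimated correlation and 0.0524 with fry, and the median was negative with scaling on hepatocyte markers, where the list was still called higher (adjusted p = 0.00411). Abcc3 lost its call without GFP 2, 3 and 5, and Nr5a2 lost its call without GFP 2, GFP 5, GFP 7 or arcA 6 (adjusted p up to 0.0733). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of 0.044 (SE 0.295, adjusted p = 0.95).

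Of 20 female-biased liver genes, 5 rose (6 adjusted over the list alone), at a median of 0.29. The list had an adjusted p of 0.429 with an estimated correlation. The genes that rose were Cyp2b9 by 0.46, Cyp2b13 by 0.59, and Cyp2c69, Cyp3a41a and Cyp3a41b as above. Of 15 male-biased genes, Ugt2b38 rose by 0.27 (0 adjusted over the list alone), and the median was 0.27. Its adjusted p was 0.592 with an estimated correlation and 0.174 with fry. The male-biased list lost its call without GFP 6 and without GFP 7 (adjusted p up to 0.0614), Ugt2b38 in 12 and Cyp2b13 in 11 of the 16 fits without 1 library (adjusted p up to 0.108).

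Of 17 immediate early genes, which respond quickly to tissue handling and stress, 4 fell (5 adjusted over the list alone), at a median of -0.087. The adjusted p was 0.287 with an estimated correlation and 0.086 with surrogate variables. Klf6 fell by 0.80, Atf3 fell by 1.61, Myc fell by 1.17 and Jun fell by 0.83, a call lost with surrogate variables. The list stayed called in each fit without 1 library, but its median was -0.027 without GFP 1, -0.014 without GFP 3, -0.047 without GFP 6, -0.16 without arcA 1 and -0.032 without arcA 5 or arcA 6. Of 20 p53 target genes, 4 fell (also 4 adjusted over the list alone), Cdkn1a (-0.74), Phlda3 (-0.88), Bax (-0.26) and Mdm2 (-0.17), at a median of -0.16. The adjusted p was 0.592 with an estimated correlation and 0.0612 with fry. Of 35 cell division genes, 1 passed with edgeR, Ccnd1 (cyclin D1), which fell by 2.54 (also the only 1 adjusted over the list alone), and the median was -0.29. The list had an adjusted p of 0.806 with an estimated correlation and 0.456 with fry, while 18 of the list's genes passed with DESeq2 and 8 with limma voom. The p53 list lost its call without GFP 6 (adjusted p = 0.0522) and without GFP 7 (adjusted p = 0.101, median -0.063). When 1 library was left out, the cell division list stayed called without GFP 1, 3, 5 or 6 or arcA 8 and lost it in the other fits of this kind; it also stayed called with the replicate block, without GFP 2, 3 and 5 and without arcA 3 and 8. Its median was 0.040 without GFP 7 (adjusted p = 0.267), -1.21 without arcA 8, and -0.19, -0.19 and -0.18 without arcA 2, 4 and 5. Bax and Mdm2 lost the call in 7 and 10 of the 16 fits without 1 library (adjusted p up to 0.0843).

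In all, camera with the preset correlation called 7 lists higher and 17 lower, and with an estimated correlation 0 higher and 6 lower, while fry, which asks whether genes of a list move on balance 1 way, called 3 higher and 13 lower. Nothing in the labels says that mice of the same group were housed or injected apart, and with 1 vector of each kind the comparison is of the arcA vector with the GFP vector.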

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

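The tests of the acute phase list, C3 and the fibrinogen genes without arcA 3 and 8 or without GFP 2, 3 and 5 were chosen only after the result was seen. Groups of 8 libraries were searched for a lowest or highest library set apart from its nearest neighbour by a large part of the group's range (Dixon's test). This singled out 30 of 358 groups (8.38%), where chance gives about 1 in 20. arcA 8 accounted for 8 of them, GFP 7 for 7, arcA 3 for 4 and GFP 2 for 3.

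arcA 8 had the lowest arcA value of Eci3 (5.75 CPM, others 10.1 to 14.9), Sqstm1 (357 CPM, others 416 to 468), Ttr (3570 CPM, others 4910 to 6100) and Gstm3 (99.4 CPM, others 177 to 280). It had the only counts of Igkv12-44 in the arcA group (0.0865 CPM). Its value was the highest for the cell division list (1.83, others -1.05 to -0.129) and the lowest for the female-biased list (-0.205, others 0.247 to 0.545). On the second principal component it lay at -25.9, with the others from -4.98 to 10.

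arcA 3 was the arcA liver with the most immune cell signal. It had the highest values of H2-Ab1 (41.2 CPM, others 7.55 to 16.7), Ccl5 (2.28 CPM, others 0.324 to 0.641), Lyz2 (50.5 CPM, others 16.8 to 26.8) and the list of MHC class II and dendritic cells (0.567, others -1.42 to -0.577). That last value lay within the GFP range (-0.011 to 1.42), as did its Kupffer cell and macrophage value (0.59, GFP 0.078 to 0.77). Its value for antigen processing and MHC class I (0.38) lay above all GFP livers (up to 0.26). For T and natural killer cells it lay below them (-0.33, GFP 0.86 to 1.96). arcA 5 had the lowest Mmp9 (0.109 CPM, others 0.591 to 1.14), and arcA 6 the lowest male-biased list value (-0.68, others 0.0523 to 0.477).

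GFP 7 had the highest GFP values of H2-DMb1 (6.04 CPM, others 3.55 to 4.32), Lpl (62.5 CPM, others 24 to 37.2), Ccnd1 (106 CPM, others 19.5 to 32.1), Bax (25.1 CPM, others 15.9 to 19.1) and the cell division list (1.74, others -0.189 to 0.361). It had the lowest value of the amino acid breakdown list (-0.351, others -0.105 to 0.0949) and lay at -30.7 on the first principal component, with the others from -20.1 to -11.2.

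GFP 2 had the lowest values of Psmb9 (19.8 CPM, others 31.8 to 41.3), Scarb2 (66.4 CPM, others 74.3 to 80.5) and the list of antigen processing and MHC class I (-0.199, others 0.0629 to 0.26). GFP 1 was lowest in Slc22a26 (1.52 CPM, others 5.2 to 11.1) and in the female-biased list (-1.92, others -0.474 to 0.157). GFP 5 was lowest in Arg1 (481 CPM, others 1320 to 1710), GFP 3 in Ly6c2 (0.12 CPM, others 0.801 to 1.61) and GFP 4 in Pdgfrb (5.26 CPM, others 7.87 to 11), while GFP 8 was highest in Cyp7a1 (122 CPM, others 34.5 to 61.8).

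The acute phase list, called higher in arcA livers with the preset correlation, was weighed against arcA 3 and 8 and against ribosomal RNA as its source. arcA 3 and 8 held the highest list values of the arcA group (1.09 and 0.873, others -0.408 to 0.289), and without both the list median fell from 0.594 to 0.0367 and the call was lost (adjusted p = 0.767). Because these libraries were left out for their high values, a drop was built in, so the lost call does not decide whether the rise was theirs alone. GFP livers had list values from -0.452 to 0.106, and of the other arcA livers only arcA 6 lay above that range. Apart from arcA 6, the list as a whole thus showed no rise beyond the GFP livers outside arcA 3 and 8. C3, Fga, Fgb and Fgg did not rest on them alone, since 4 of the 4 stayed called without them, at 0.53, 0.46, 0.46 and 0.42. Ribosomal RNA in GFP 2, 3 and 5 was argued against, since the list median was 0.664 without them, and an effect of arcA on C3 and the fibrinogen genes stays open as a hypothesis.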

How the results depend on the processing

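The fits without GFP 2, 3 and 5, without arcA 3 and 8, with counts halved, without Gm42418 and Lars2, and with scaling on hepatocyte markers were chosen only after the result was seen. Of 132 named genes past the threshold, 100 kept call and direction in each of the 16 fits that left out 1 library, 76 did so in all alternatives run for them, and 0 changed direction. Calls were lost by 35 without GFP 2, 3 and 5, 30 with scaling on hepatocyte markers, 27 with library size alone, 23 with surrogate variables, 20 with the replicate block, 16 without arcA 3 and 8, 13 with no filter, 12 with counts halved, 4 with limma voom and 0 with DESeq2.

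The 618 higher and 951 lower genes became 56 and 662 with a fold of at least 1.5, which by construction removes small changes. Higher genes numbered 253 with library size alone, 407 with a filter of 1 CPM in at least 8 libraries and 369 without GFP 2, 3 and 5, and from 389 (without GFP 2) to 638 when 1 library was left out; lower genes then ranged from 731 to 1046. Scaling on hepatocyte markers gave 94 higher and 2729 lower genes; it moved the median of all genes from 0.0091 to -0.15, and small rises are to be read against that shift. For the other changes the cause was not tested. RLE scaling (540 and 979), DESeq2 (780 and 1414), limma voom (832 and 1147) and surrogate variables (682 and 910) stayed within 1.5 times. In random divisions of the 16 libraries into 8 and 8, 1 of 60 divisions, the real one, gave as many higher genes and 1 of 60 as many lower genes, with at most 0 in the others. The smallest share that 60 divisions can show is 1 of 60, so chance is unlikely for the gene counts but not excluded. For the numbers of lists called by camera with the preset correlation, chance stays a possible source: 55 of 60 gave at least 7 and 4 of 60 at least 17, and the highest other number was 18.

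The 7 higher lists became 0 with an estimated correlation, 3 with fry and 14 with scaling on hepatocyte markers, and the 17 lower lists 6 with an estimated correlation; leaving out 1 library gave 6 to 10 and 15 to 17. Of the 24 lists called, 20 kept call and sign in each of those fits. The list median turned to -0.032 for amino acid breakdown, -0.012 for methionine and one-carbon metabolism and -0.052 for bile acid synthesis and transport with scaling on hepatocyte markers, and for cell division it ranged from -1.21 to 0.040 when 1 library was left out. Among lists not called, urea cycle and arginine transport or breakdown was called in 0 of 28 alternatives (adjusted p 0.0687 to 0.604), the ATF4 targets in 1 (fry, 0.0376), lysosome in 2, periportal hepatocytes in 12 and autophagy in 0.

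Of genes not past the threshold, 7 changed sign. The log2 fold change of Scd1 was -0.026 with library size alone, -0.26 without GFP 2, 3 and 5, -0.12 with scaling on hepatocyte markers, and -0.12 to 0.34 with 1 library left out. It was 0.60 with surrogate variables, where it passed (adjusted p = 0.0414, range over the alternatives 0.0414 to 0.994). That of Pck1 was -0.13 with surrogate variables, -0.075 with scaling on hepatocyte markers, and -0.019 to 0.15 with 1 library left out; Cyp7a1 gave -0.081 without GFP 2, 3 and 5, -0.093 with that scaling, and -0.11 to 0.27. Srebf1 gave -0.00071 without GFP 2, 3 and 5 and -0.050 with that scaling, Map1lc3b -0.082 and Sqstm1 -0.079 with that scaling, and Lcn2 -0.32 without arcA 3 and 8. The causes were not tested.

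Pairing of the mice by replicate number was not detected, which does not show that it is absent. Same-numbered libraries deviated with r from -0.049 to 0.16, 2 of 8 pairs over 0.1, and 2 of 8 GFP libraries correlated best with their own number. With the replicate block, 592 genes were higher and 876 lower, and 9 and 16 lists were called; among named genes, Serpinb1a (adjusted p = 0.07) and Apoa4 (adjusted p = 0.0704) lost the call in this alternative only, and the p53 list lost its call too (adjusted p = 0.0613). The sex covariate was not run, because no library stood apart by sex. Depth limits genes such as Fgf21 and Asns, which the filter left out of the comparison of all 16 libraries; both were tested with no filter and with DESeq2, and Fgf21 also in some fits with fewer libraries. Among lists with members past the threshold in edgeR, their numbers differed by over 1.5 times with both DESeq2 and limma voom for several. These were cell division (18 and 8, edgeR 1), amino acid breakdown (9 and 8, edgeR 5) and xenobiotic metabolism (7 and 8, edgeR 4). The same held for antigen processing and MHC class I (4 and 4, edgeR 2), male-biased genes (3 and 4, edgeR 1) and fatty acid oxidation (4 and 3, edgeR 1). Where edgeR passed 0, DESeq2 and limma voom passed 2 and 2 members of the urea cycle and arginine list and 2 and 2 heat shock proteins. They also passed 3 and 2 periportal hepatocyte genes, 4 and 1 major urinary proteins, 2 and 1 bile duct cell genes and 1 and 1 circadian clock genes.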

Other observations

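The tests of ribosomal RNA on immune cell genes and on risen genes, of the share of hepatocytes, of dilution and of a response to the GFP vector were chosen only after the result was seen. Some gene groups outside the main lists moved in small numbers. Of 24 lipoprotein and sterol export genes, 1 rose and 3 fell (3 and 4 adjusted over the list alone), namely Lcat at 0.30, Mylip at -0.61, Apoc2 at -0.38 and Abcg1 at -0.86 on the log2 scale, and the list was not called (adjusted p = 0.979). Of 15 genes of the growth hormone and IGF axis, Igfals, Ghr and Stat5b rose by 0.60, 0.23 and 0.23 and Igfbp3 fell by 0.57 (list adjusted p = 0.452; 4 rose and 1 fell adjusted over the list alone). Of 38 xenobiotic metabolism genes, Ugt1a1, Cyp2e1 and Cyp3a13 rose by 0.46, 0.37 and 0.42 and Gstm3 fell by 1.01 (list adjusted p = 0.157; also 3 and 1 adjusted over the list alone). Of 20 NRF2 targets, Srxn1 and Hmox1 had log2 fold changes of -0.48 and -0.63 and Cat rose by 0.25 (list adjusted p = 0.946; 2 rose and 3 fell adjusted over the list alone). Calls of Stat5b, Cyp3a13, Gstm3 and Cat were lost in 9, 6, 14 and 10 of the 16 fits without 1 library (adjusted p up to 0.0981). Ghr, Igfbp3 and Car3 lost the call without GFP 2, 3 and 5, Lcat with scaling on hepatocyte markers, and Hmox1 and Apoc2 with surrogate variables. The xenobiotic list was called in 3 of 28 alternatives. The adipocyte list was not called (adjusted p = 0.564), though Retn, which encodes resistin, rose by 1.68 and Car3 by 0.37 (2 rose and 1 fell adjusted over the list alone). Of 5 tested neutrophil genes, Mmp9 rose by 1.51 (also the only 1 adjusted over the list alone; list adjusted p = 0.402), with the call lost in limma voom, with surrogate variables, without arcA 3 and 8 and with the replicate block (adjusted p up to 0.0978), and Lcn2 had a log2 fold change of 1.90 (SE 0.765, adjusted p = 0.135) with 379 ± 567 CPM in arcA livers (SD, n = 8). arcA 3 and arcA 8 had 1007.5 and 1528.2 CPM of Lcn2 and the other arcA livers 43.1 to 146, 4 of 8 lay above the GFP median, and the log2 fold change was 1.08 without arcA 8.

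The other lists held few calls. Of 17 pericentral hepatocyte genes, Cyp2e1 and Avpr1a rose, Avpr1a by 0.78, and Gstm3 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.0821, called in 5 of 28 alternatives). Of 16 periportal hepatocyte genes, 0 passed with edgeR (3 rose adjusted over the list alone; 6 had an unadjusted p under 0.05, 3 passed with DESeq2 and 2 with limma voom; list adjusted p = 0.0552). Of 26 endoplasmic reticulum chaperone genes, Edem1 and Pdia4 rose by 0.20 and 0.25 (also 2 adjusted over the list alone; list adjusted p = 0.203). Of 14 polyamine genes, Paox rose by 0.26 (2 rose and 1 fell adjusted over the list alone; list adjusted p = 0.818). Of 15 glucocorticoid targets, Cdkn1a and Sult1e1 fell, Sult1e1 at -0.60 (also 2 adjusted over the list alone; list adjusted p = 0.979). Of 13 mitochondrially encoded transcripts, mt-Nd1 fell by 0.30 (also the only 1 adjusted over the list alone; list adjusted p = 0.946), and of 2 skeletal muscle genes, too few for a list test, Des fell by 0.52, a call lost without GFP 2, 3 and 5. Calls of Avpr1a, Paox, Edem1, Pdia4 and Sult1e1 were lost in 8, 12, 2, 11 and 5 of the 16 fits without 1 library (adjusted p up to 0.113). With edgeR, 0 genes passed, over all genes or adjusted over the list alone, in 10 further lists. At an unadjusted p under 0.05 they held 7 genes of gluconeogenesis, 5 heat shock proteins, 1 nuclear-encoded respiratory chain gene, 2 cytosolic ribosomal proteins, 3 circadian clock genes, 2 major urinary proteins, 4 bile duct cell genes, 1 red blood cell gene, 0 pancreatic exocrine genes and 0 sex chromosome genes. In the same order, DESeq2 passed 2, 2, 0, 0, 1, 4, 2, 0, 0 and 0 genes of these lists and limma voom 0, 2, 1, 2, 1, 1, 1, 0, 0 and 0.

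The immunoglobulin reads of GFP livers came from many variable segments. Over 103 kappa variable segments, each GFP liver had 772 to 6314 counts and each arcA liver 12 to 46. Over 108 heavy chain variable segments, the ranges were 331 to 3217 and 8 to 19. The leading kappa segment took 14% to 37.6% of a GFP liver's kappa counts and was 1 of 7 different segments across the 8 livers; the leading heavy chain segment took 16.1% to 43.8%, also with 7 different ones. Immunoglobulin genes together took 0.0373% ± 0.0298 of counts in GFP livers and 0.000682% ± 0.000146 in arcA livers (SD, n = 8 each).

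The lower level of immune cell genes in arcA livers was weighed against 3 explanations. Ribosomal RNA in GFP 2, 3 and 5 was argued against: over 83 genes of 6 immune cell lists, the median log2 fold change was -1.22 with these libraries and -1.26 without them, and 48 of 55 called genes stayed called. A lower share of hepatocytes in GFP livers would raise genes of every other cell type alike. As the whole source it was argued against, since lists of other cell types did not move alike. Their medians included -2.98 for T and natural killer cells, -0.67 for Kupffer cells and macrophages and -0.36 for stellate cells. Bile duct cells had 0.078 and neutrophils, with 5 tested genes, 0.84. T and natural killer cell genes differed by -2.61 log2 units more than sinusoidal endothelial genes. Both lists were picked after their values were seen, so the two-sided exact permutation p of 0.00016 carries no weight. It was the smallest that 8 against 8 can give. All 21 sinusoidal endothelial genes had negative log2 fold changes, at a median of -0.22, so a smaller part stays open. An immune response to the GFP vector in the control livers and a reduction of immune cells by arcA cannot be told apart, because 0 groups received no vector or an empty one. A lower count of lymphocytes and macrophages in arcA livers than in GFP livers may underlie the pattern, which stays a hypothesis found and tested on the same data.

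The modest rises of the 618 genes called higher were weighed against dilution by RNA of other cells in GFP livers and against ribosomal RNA. For dilution, the shares of counts cannot decide, and no verdict is drawn. A rise of 0.267, the median over these genes, needs 16.9% of the counts of GFP livers to come from other cells. The genes called lower held at most 2.86% of the counts of a GFP liver, which by itself allows a rise of 0.0418. Falls in share summed over all genes, called or not, came to 5.41% of counts without Gm42418 and Lars2. RNA of other cells in genes that did not fall was not counted, so these shares set no upper limit on dilution. Over the 8 GFP livers the shares of the lower and the higher genes were inversely related (Spearman -0.786), as dilution would give. Dilution thus stays open as a source, in whole or in part. Scaling on hepatocyte markers (median 0.108, 94 still called) shifts all genes alike and does not decide this. For ribosomal RNA in GFP 2, 3 and 5 as the source, no verdict is drawn. A first condition, which asked for at least as many calls kept as lost, was not met. It was replaced by a second one after that was seen, because any loss of 3 libraries ends calls. Without these libraries the median was 0.269, and 301 of the 618 stayed called. Over all 56 sets of 3 GFP libraries left out, 40 kept 301 or fewer; the other sets kept a median of 253 (119 to 458) at medians of 0.237 to 0.303. The calls thus ended no more often than with other libraries left out. The medians changed little with any set left out, as the genes were picked with all libraries, so the medians cannot decide. An effect of arcA on these genes stays open as a hypothesis.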
